A study of Betula luminifera with 4 samples.

How the data were processed

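Poly(A) RNA was sequenced as read pairs from 1 root and 1 shoot library per medium, 4 libraries, per the labels' protocols; shoot RNA was stem and leaf RNA pooled in equal amounts. The protocols name a randomized block layout of 54 plants, but the number of plants behind each library and the length of the treatment are not given in the sources used here. Reads were handled with cutadapt 1.9 and FastQC, per the submitters' processing notes. The deposited table gives TPM per assembled gene, a length in base pairs and protein annotations, per the file headers. Gene identifiers have the form that the assembler Trinity gives; the assembler, aligner and quantifier are not given in the sources used here, and no genome was used. Because TPM are shares of a fixed total in every library, RNA of any other organism lowers the values of birch genes in that library.

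TPM keep no depth of their own. At equal length, however, the values of single-transcript genes lie on whole multiples of a smallest step, which is what 1 fragment is worth; within 0.0065 TPM, 89.4% of low values in CK roots, 97.2% in LP roots, 96.9% in CK shoots and 98.2% in LP shoots were whole multiples, against 2.83%, 4.82%, 2.56% and 3.26% by chance. By these steps 3 fragments of a 400 bp contig were 0.513 TPM in CK roots, 0.266 in LP roots, 0.630 in CK shoots and 0.530 in LP shoots. A gene of 10 TPM and 400 bp had a relative counting error of 13.1%, 9.42%, 14.5% and 13.3% in the same order. This covers counting error only and takes each fragment as a separate molecule. Whether the CK root library held few distinct fragments was left open, so its error may be larger.

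Libraries were grouped by the tissue and medium of their labels. The comparisons were LP against CK in roots and in shoots, the overlap of these, and roots against shoots in each medium. A gene was called when its larger value was at least 1 TPM and its log2 ratio, with a pseudocount of 1 TPM, was at least 1 in size; the log2(value + pseudocount) scale understates changes of low genes. No p-value, standard error or spread between replicates was computed, because each group is 1 library. Intervals of list medians are 95% intervals over the members of a list, from binomial order statistics, and SDs and interquartile ranges are taken across genes; both describe genes within these libraries and leave out variation between plants. Gene lists (27) were fixed by patterns in the protein names before the data were examined. Members are genes of at least 1 TPM in some library, and each list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on the mean log2 value in 20 bins, as a description of these libraries. A member undetected in both libraries compared stays in its list, counts as unchanged and pulls the median toward no change. With 27 lists, 2 tissues and both gene sets, 108 medians were computed. In roots 5 of the 27 lists lay outside percentiles 2.5 to 97.5 over all members and 6 over birch-like members; in shoots 8 and 11 did. The list meant for non-plant sequences matched mainly retrovirus-related transposon proteins and is not described.

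Named genes followed a rule also fixed beforehand: in each comparison the 8 highest and 8 lowest log2 ratios with at least 5 TPM and a protein name, the most abundant higher and lower member of each list, and the most abundant gene of each protein name in the 4 phosphate lists (transport, SPX, phosphatases and nucleases, lipid remodelling); between tissues, the 3 genes with the largest opposite ratios. That rule gave more genes than fit the text, so the 8 most abundant of each phosphate list, its most abundant higher and lower members and the 2 highest and 2 lowest ratios are named, a narrowing chosen after the data were seen. Several contigs can carry the same protein name, so reads of related genes may be split between them.

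The organism of the best Nr or Swiss-Prot match sorted genes into eudicot (called birch-like), yeast, other fungus, animal, slime mould, other and none. This sorting, the counts restricted to birch-like genes, scaling by the median of ratios over birch-like genes, and counts of genes above 0 in every library compared were chosen after the data were seen. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum of 5 TPM, median scaling over all genes, a log2 threshold of 2, and sums over genes that share a protein name. The calling and list steps were tested on simulated data made from the 26980 birch-like genes above 0 in the CK shoot library. An SD of 0.3 log2 units between libraries was assumed, which fixes the rates and which no replicate measures. All 4-fold changes were called (100%), 2.0% of 1.5-fold changes were, and 0.0299% of 26780 unchanged genes. The changes were planted in genes of at least 5 TPM, and no counting error or zeros were added. The rates of changed genes therefore do not cover low genes, and none covers genes listed at 0 or the root libraries. Over birch-like genes of at least 1 TPM in all 4 libraries, the log2 ratios themselves had an SD of 0.89 in shoots and 1.56 in roots, treatment included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.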

Results

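RNA was measured in a clone of the birch Betula luminifera grown from tissue culture in sand. Plants were watered with a mineral medium that held 1.25 mM phosphate (CK) or with the same medium lacking phosphate (LP), in which potassium sulfate made up the potassium. For both media the sample records give seedlings 2 months old and, before the treatment, 2 weeks on normal medium and 2 weeks on water. For each medium there was 1 root library and 1 shoot library, the latter from stem and leaf RNA mixed in equal amounts, 4 libraries in all. The comparisons ask how roots and shoots differ in their response to missing phosphate. With 1 library per group there is no spread between replicates, so every difference compares these libraries and has no replicate check. A gene was called higher or lower when its larger value was at least 1 TPM and its log2((LP + 1)/(CK + 1)) was at least 1 in size.

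The assembled transcriptome listed 76899 genes. Above 0 were 26711 of them in the CK root library, 56647 in the LP root library, 39046 in the CK shoot library and 50435 in the LP shoot library. For a contig of 400 bp, 1 TPM corresponded to 5.85 fragments in CK roots, 11.3 in LP roots, 4.76 in CK shoots and 5.66 in LP shoots. The best protein match was a eudicot for 34242 genes, and these are called birch-like here; they held 66.0% of the TPM in CK roots, 51.5% in LP roots, 82.4% in CK shoots and 78.7% in LP shoots. Restricting counts and lists to birch-like genes was chosen after the data were seen, so planned values over all genes or members are given as well for most counts, sums and list medians. Genes whose best match was an animal protein numbered 1670 in LP roots and 1638 in LP shoots at 1 TPM or more, against 148 in CK roots and 95 in CK shoots. By amount they held 0.915% of the TPM in LP roots, 1.29% in LP shoots, 0.973% in CK roots and 0.121% in CK shoots, so the root libraries held about as much. Yeast-matched genes numbered 1323 in LP roots, 105 in CK roots, 111 in LP shoots and 35 in CK shoots. By amount they held 2.53%, 0.622%, 0.158% and 0.0947% of the TPM in the same order. Over birch-like genes of at least 1 TPM in all 4 libraries, median scaling placed the LP root library 0.63 log2 units below the CK root library and the LP shoot library 0.11 above the CK shoot library. Log2 ratios below are as deposited; values called scaled are relative to those shifts.

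**Figure D1:**
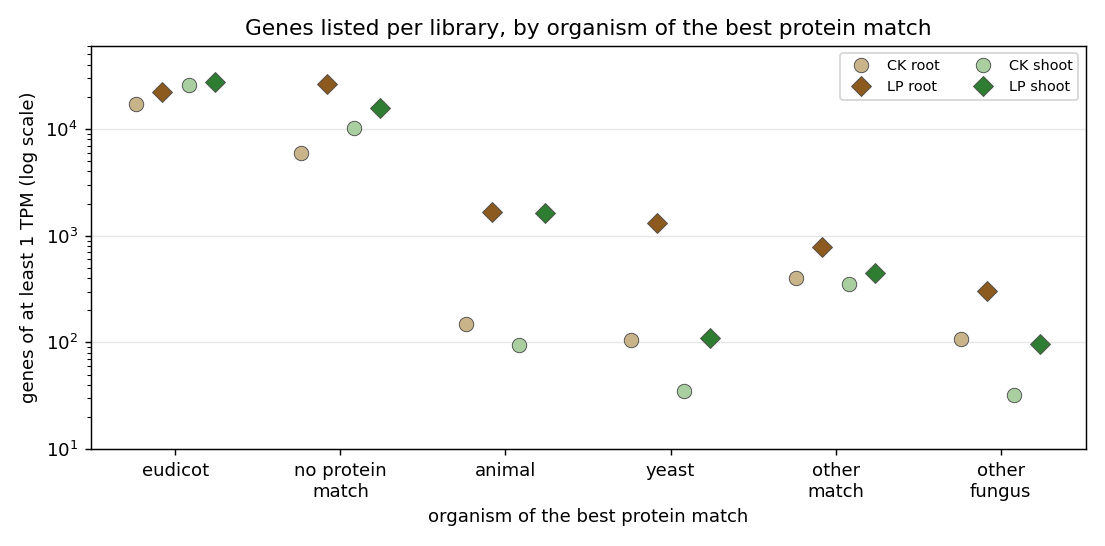
Number of genes of at least 1 TPM per library (log axis) by the organism of the best protein match; circles are CK libraries and diamonds LP libraries, brown for roots and green for shoots. Animal-matched genes numbered 148 and 95 in the CK libraries and 1670 and 1638 in the LP libraries, and yeast-matched genes stood at 1323 in the LP root library.

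In shoots without phosphate, 17 of 49 phosphate transport genes were higher and 8 lower, as were 2 and 0 of 8 SPX genes. Of 81 phosphatases and nucleases 30 were higher and 14 lower, and of 43 lipid remodelling genes 17 and 4. GDPD1, a glycerophosphodiester phosphodiesterase that breaks down products of phospholipids, rose from 2.28 to 89.3 TPM, a 39.2-fold ratio. A contig of the purple acid phosphatase PAP3 of 1251 bp rose from 6.74 to 105 TPM while another of 222 bp fell from 40 to 1.36 TPM, and the phosphate importer PHT1-1 from 8.07 to 60.1 TPM. Genes of cell division were lower: 52 of 94 birch-like members of the cell cycle list fell and 8 rose, as did 60 and 14 of all 119 members. Histone H2B (HIS2B) went from 517 to 167 TPM.

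Phosphate transporters made up 49 listed genes, of which 37 were birch-like. Among the birch-like members 16 rose, 6 fell and the median log2 ratio was 0.52, at percentile 99.3 of random lists matched on expression. Over all 49 members the median was 0.00 (percentile 44.2). Listed at 0 in both shoot libraries were 12 of the 49 members and 5 of the 37 birch-like ones. Birch-like root markers in the same libraries had 12 members higher and 4 lower, with a median of 0.19 (percentile 96.4) and sums of 2378 and 3097 TPM. These markers told roots from shoots weakly: under CK 18 of 45 were higher in roots and 9 in shoots. Besides PHT1-1 (log2 ratio 2.75), the importers PHT1-3 (a contig of 712 bp, 17.8 to 88.9 TPM, log2 ratio 2.26) and PHT1-4 (19.3 to 52.4 TPM, 1.40) rose, as did PHO1, which loads phosphate into the xylem (13.9 to 38.9 TPM, 1.42), and the anion transporter ANTR4 (13 to 34.9 TPM). Another PHT1-3 contig, of 281 bp, stood at 2.63 TPM in CK and was listed at 0 in LP. PHT1-7, a contig of 251 bp, went from 15.4 to 32.8 TPM, a log2 ratio of 1.04 that was 0.92 when scaled. The chloroplast transporter PHT2-1 stood at 41.4 and 29.7 TPM, and the PHO84-like transporter at 24.2 and 20.0 TPM, neither past the size rule, and the anion transporter ANTR3 fell from 20.2 to 6.65 TPM.

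SPX proteins bind inositol pyrophosphates and so report cellular phosphate. Of 7 birch-like members 2 rose and none fell, with a median of 0.74 (percentile 97.7); with the single further member the median was 0.51 (percentile 96.8). A contig named SPX2 rose from 6.06 to 57.0 TPM, while a more abundant SPX2 contig went from 63.8 to 118 TPM (log2 ratio 0.87) and the membrane protein At4g22990 from 22.8 to 38.7 TPM (0.74), short of the rule. SPX3 was listed at 0 in CK and at 19.0 TPM in LP, and SPX4 stood at 16.7 and 18.8 TPM.

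Acid phosphatases and some nucleases release phosphate from organic sources. The name pattern of this list also took in RNA-processing enzymes, such as the exoribonuclease XRN3 and ribonuclease 3-like proteins, which count among its members. Of 78 birch-like members 29 rose and 14 fell, with a median of 0.37 (percentile 97.7); over all 81 members it was 0.28 (percentile 91.8). The longer PAP3 contig (log2 ratio 3.78), PAP27 (11 to 43.7 TPM, 1.89) and the inorganic pyrophosphatase At1g17710 (28.8 to 96.8 TPM, 1.72) rose. The shorter PAP3 contig (-4.12) was the most abundant member that fell, and summed over all contigs of its protein name PAP3 had a log2 ratio of 0.96, short of the rule. PAP18 (115 and 124 TPM) was level and its ratio was 0.00 when scaled, and PAP26 (89.8 and 78 TPM), APS1 (68.4 and 51.0 TPM), PAP29 (35.9 and 53.8 TPM) and XRN3 (51.5 and 57.8 TPM) stayed within the rule.

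Enzymes that replace phospholipids by galactolipids and sulfolipids gave the list with the highest percentile among the 4 phosphate lists. Of 37 birch-like members 17 rose and 3 fell, with a median of 0.87 (percentile 100); over all 43 members the median was 0.66 (percentile 99.9). DGD1, a digalactolipid synthase, rose from 56.0 to 159 TPM (log2 ratio 1.49), and SQD2, which makes sulfolipid, from 16.3 to 43.7 TPM (1.37). SQD1, which makes the sulfolipid head group donor, went from 38.9 to 70.7 TPM (0.85). The abundant GDPDL1 (312 and 442 TPM), GDPDL3 (260.8 and 340.8 TPM) and NPC1 (138 and 167 TPM) and the less abundant GDPDL4 (51.3 and 27.5 TPM) did not pass the rule. GDPDL7, whose best match was not a eudicot, stood at 39.6 TPM in CK and was listed at 0 in LP. Regulators of phosphate starvation also stood high, with 9 of 26 members higher, 1 lower and a median of 0.64 (percentile 99.8), the same over all members, as each was birch-like; the SUMO ligase SIZ1 rose from 21.0 to 70.7 TPM, and LPR1 was at 22.8 TPM in CK and listed at 0 in LP.

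The birch-like lists below percentile 2.5 in LP shoots were photosynthesis, cell wall loosening, cytosolic ribosome, auxin and cell cycle. The 63 birch-like nuclear photosynthesis genes summed to 52938 TPM in CK and 33891 in LP; their median was -0.54 (percentile 0.02), with 15 members lower and 9 higher, and over all 70 members it was -0.56 (percentile 0). A chlorophyll a-b binding protein (OsI_012078) fell from 3234 to 1612 TPM. Of 112 birch-like cell wall loosening genes 34 fell and 16 rose (median -0.27, and -0.26 over all 113 members), among them expansin EXPB3 (176 to 30.1 TPM) and, upward, XTH30 (11.5 to 49.2 TPM). The auxin receptor TIR1 fell from 210 to 86.6 TPM and auxin response factor ARF25 rose from 24 to 55.7 TPM, in a list of 131 with 28 lower, 17 higher and 86 neither (median -0.14, percentile 1.60 among birch-like genes and 0.84 among all genes). The median of the cell cycle list was -1.63 for birch-like members and -1.03 over all 119 members, both at percentile 0. Of 297 birch-like cytosolic ribosomal protein genes 31 were lower and 32 higher (median -0.16, percentile 0). Over all 714 members the median was 0.00 (percentile 50), with 216 of them listed at 0 in both shoot libraries. Organelle transcripts had 90 of 187 members higher and 13 lower (median 0.90, percentile 100), and the 66 birch-like ones a median of 0.40 (percentile 89.6). Birch-like heat shock genes had a median of 0.22 (percentile 98.7), and all 199 members 0.11 (percentile 98.6); ClpB3 (CLPB3) went from 42 to 89.1 TPM (log2 ratio 1.07, 0.96 when scaled) and HSP70-17 fell from 55.4 to 25.2 TPM.

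Over the whole table, 21508 of 53571 genes were higher in LP shoots and 12325 were lower. Among 30737 birch-like genes 8120 were higher and 6484 lower, or 7510 and 6862 with median scaling. Genes without any protein match accounted for 11286 of the higher calls and animal-matched genes for 1632, and TPT1 (listed at 0 in CK, 94.2 TPM in LP) was an animal match among the highest ratios of genes with a protein name. HERK1, a receptor-like kinase contig of 233 bp, was listed at 0 in CK and at 110 TPM in LP; a proteinase inhibitor of the PSI-1.2 type (115 TPM) and the tropinone reductase homolog At2g29290 (101 TPM) were listed at 0 in LP.

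**Figure D2:**
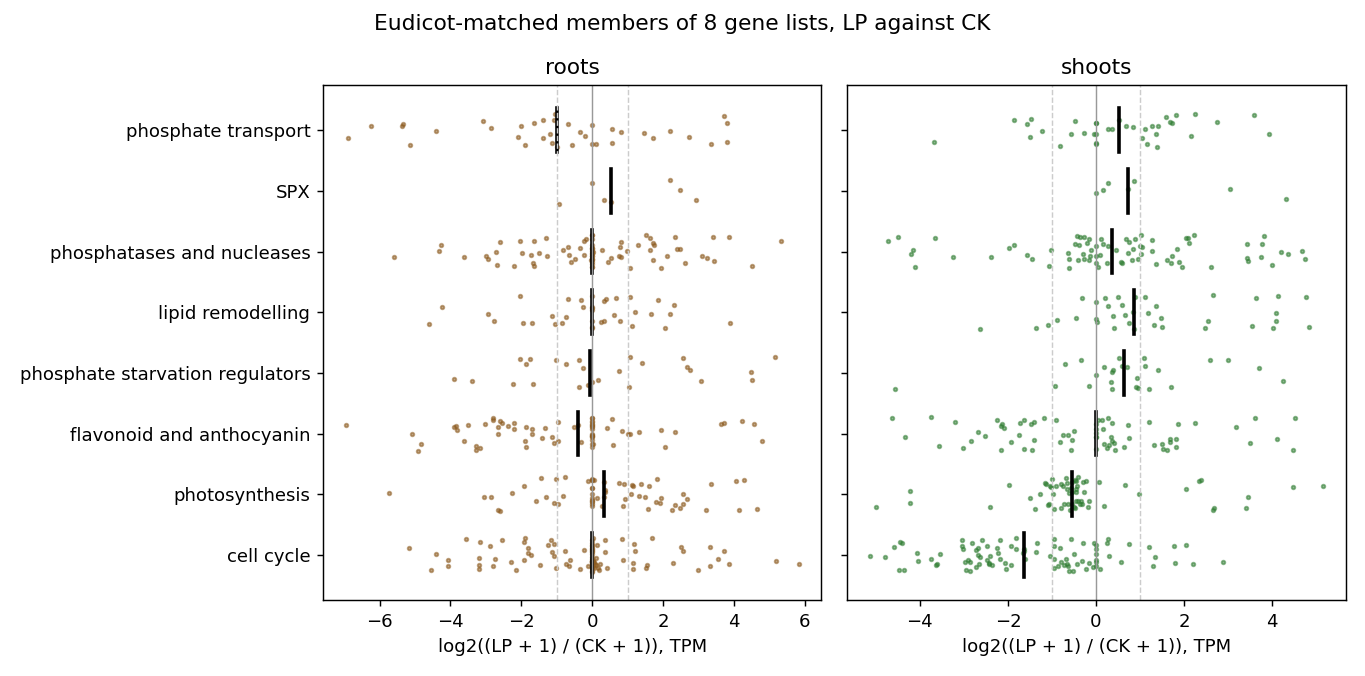
Log2((LP + 1)/(CK + 1)) of TPM for the birch-like members of 8 gene lists in roots (brown) and shoots (green), as deposited; each point is a gene, black bars are medians, and dashed lines mark the size rule at -1 and 1. The phosphate transport median was -0.98 in roots (-0.39 when scaled) and 0.52 in shoots, and the cell cycle median in shoots was -1.63.

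In roots, members of the phosphate lists moved both ways. The phosphate importer PHT1-4 fell from 116 to 12.9 TPM, and the phosphatase PAP15 from 118 to 4.90 TPM. The SPX membrane protein At4g22990, thought to carry phosphate across the vacuole membrane, rose from 16.0 to 76.6 TPM, and a PHO84-like transporter from 4.22 to 67.7 TPM. Among 69 birch-like flavonoid genes 31 were lower, 11 higher and 27 neither, and the median of -0.40 was 0.00 when scaled. The LP root library was also the one with 1323 yeast-matched and 1670 animal-matched genes, which held 2.53% and 0.915% of its TPM. Genes with no protein match held 43.3% of its TPM against 29.0% in CK roots, while the birch-like share was 51.5% against 66.0%.

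Of 37 birch-like phosphate transporters 18 were lower and 8 higher in LP roots, and the median of -0.98 (percentile 0.58) became -0.39 when scaled, with 12 lower and 10 higher. Over all 49 members the median was -0.19 (percentile 0.18), and 0.00 with median scaling. Birch-like root markers had 20 of 45 members lower and 7 higher in the same libraries. PHT1-5 (54.7 to 12 TPM, log2 ratio -2.10) fell with PHT1-4 (-3.07). PHT1-4, PHT1-5, PHT1-7 and the PHT1-3 contig of 281 bp share the first part of their assembly identifier. They may share reads, so their falls are not independent. The PHT1-3 contig of 281 bp went from 94.4 to 44.2 TPM (-1.08, -0.46 when scaled), that of 712 bp from 72.8 to 19.0 TPM (-1.89) and PHO1 from 155 to 95.7 TPM (-0.69). PHT1-8 (231 bp) stood at 117 TPM in CK and was listed at 0 in LP, and PHT1-7 (251 bp) went from 97.45 to 0.30 TPM. Of the 18 lower transporters 7 were contigs under 400 bp and 5 were listed at 0 in LP roots; among members of at least 1000 bp 5 were lower and 2 higher. PHO87, at 78.6 TPM in LP and listed at 0 in CK, was a yeast match.

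SPX genes in roots had 3 of 7 birch-like members higher and none lower, with a median of 0.55 (percentile 96.6); over all 8 members it was 1.37 (percentile 97.2). SPX4 (18.4 and 9.24 TPM) and SPX2 (13.4 and 17.3 TPM) stayed within the rule, SPX3 was listed at 0 in both root libraries, and the membrane protein OsI_17046 was listed at 0 in CK and at 6.67 TPM in LP. Acid phosphatases and nucleases had 21 of 78 birch-like members higher and 19 lower, with a median of 0.00. Over all 81 members it was 0.00 too (24 higher, 19 lower), and 19 members were listed at 0 in both root libraries. Over all members above 0 in both, the unscaled median was -0.82, and no scaled value was computed. Median scaling placed the LP root library 0.63 log2 units below the CK root library. PAP28 fell from 93.3 to 0.96 TPM and a contig named 3'-5' exoribonuclease 1-like from 28.8 to 6.59 TPM, as did a contig named probable inactive purple acid phosphatase 27 (47.7 to 5.07 TPM), while PAP22 (208 bp) was listed at 0 in CK and at 39.4 TPM in LP. PAP9 stood at 40 and 71.1 TPM (log2 ratio 0.82, 1.43 when scaled), PAP18 at 87.8 and 68.4 TPM (-0.36, but 0.26 when scaled) and XRN3 at 68.5 and 38.4 TPM.

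Among lipid remodelling genes 9 of 37 birch-like members were higher and 9 lower in LP roots, with a median of 0.00, as over all 43 members (12 higher, 11 lower). NPC2, a phospholipase C, fell from 93.5 to 2.88 TPM, DGD1 from 30.9 to 3.68 TPM and GDPDL1 from 242 to 73.6 TPM. Phospholipase D zeta 2 (PLPZETA2), whose best match was not a eudicot, fell from 63.8 to 8.99 TPM, and GDE1, a yeast match, stood at 82.7 TPM in CK and was listed at 0 in LP. NPC1 rose from 117 to 247 TPM. GDPDL3 went from 350 to 159 TPM, a log2 ratio of -1.13 that was -0.51 when scaled, and GDPD1 from 37 to 21.8 TPM. A phosphate regulator named PHR1-LIKE 1-like isoform X1 rose from 1.04 to 44.6 TPM and another contig of the PHR1-LIKE 1 type fell from 74.4 to 6.23 TPM; 10 of the 26 regulators were higher and 8 lower.

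The flavonoid list had a median of -0.40 over birch-like members (percentile 0), and 0.00 when scaled with 28 members lower and 13 higher; over all 70 members it was -0.46 (percentile 0). Within it, the glucosyltransferase GT5 fell from 140 to 3.69 TPM and anthocyanidin reductase (BAN) rose from 33.5 to 142 TPM. The root markers had a median of -0.79 (percentile 0.885) that was -0.17 when scaled, and -0.77 over all 46 members; the aquaporin PIP1-2 went from 938 to 404 TPM (log2 ratio -1.21, -0.59 when scaled) and the developmental regulator AIL1 rose from 5.27 to 182 TPM. Birch-like photosynthesis genes had a median of 0.32 (percentile 99.8), but over all 70 members the median of 0.30 lay at percentile 88.3. OsI_012078 rose from 187 to 3698 TPM in roots. Without that gene the list summed to 682 TPM in CK roots and 461 TPM in LP roots. Cytosolic ribosomal protein genes had a median of 1.85 over all 714 members (percentile 100) but -0.75 over the 297 birch-like ones (percentile 0), or -0.16 when scaled with 107 lower and 102 higher. RPL17B fell from 732 to 234.3 TPM, and RPS29, the highest ratio in roots among genes with a protein name, was a yeast match listed at 0 in CK and at 514 TPM in LP.

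Among all genes, 37681 of 58668 genes were higher in LP roots and 13169 lower, so 74.1% of the calls were higher. Among 25251 birch-like genes 10098 were higher and 8525 lower (54.2% higher), which became 11797 and 6587 with median scaling (64.2% higher). Among genes above 0 in both root libraries the balance turned, with 5113 higher and 8542 lower. Of the higher calls 23663 had no protein match, 1290 were yeast-matched and 1644 animal-matched. Among genes with a protein name, the lowest ratios were of short contigs listed at 0 in LP, a cytosolic sulfotransferase 12-like contig of 202 bp at 338 TPM and laccase LAC22 of 212 bp at 263 TPM in CK; the ADP,ATP carrier AAC was listed at 0 in CK and at 187 TPM in LP.

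**Figure D3:**
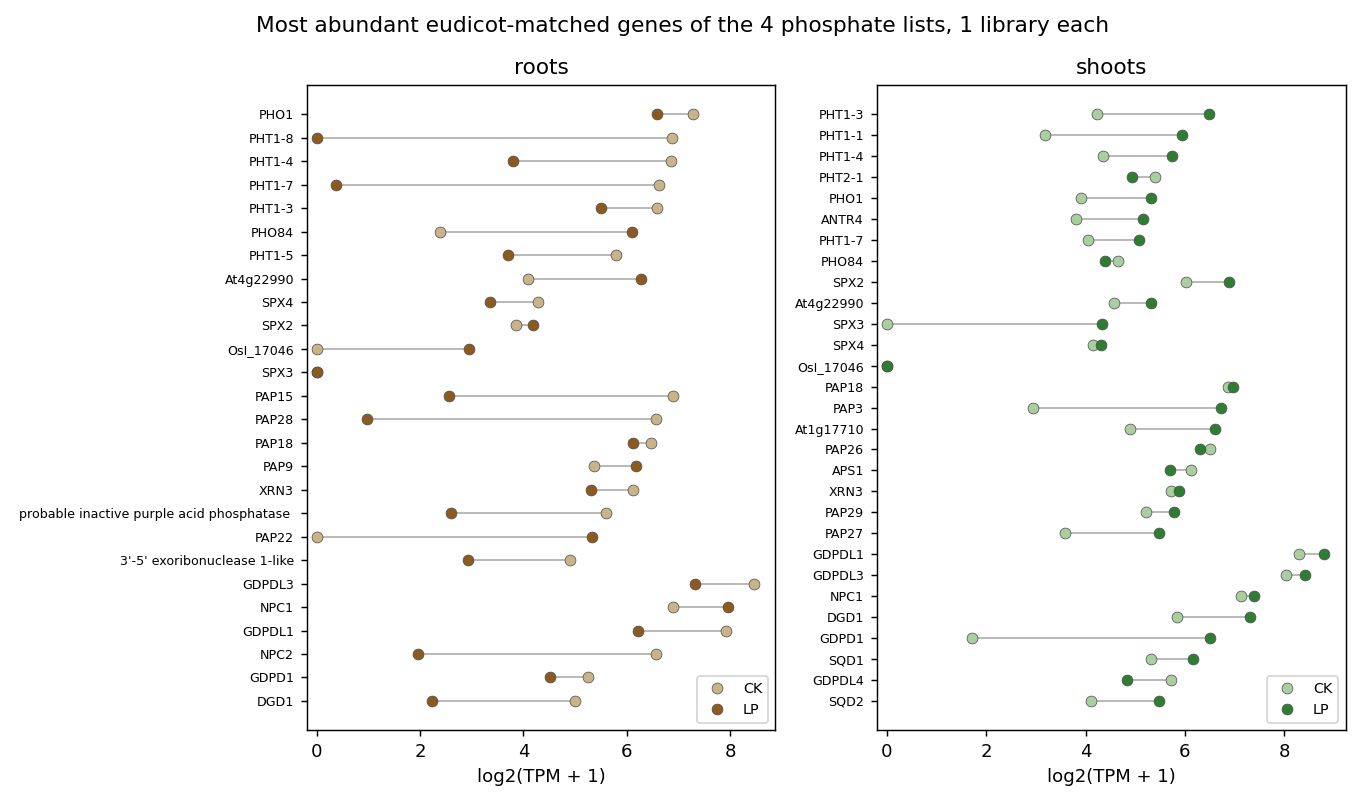
Log2(TPM + 1) of the most abundant birch-like genes of the 4 phosphate lists in roots and shoots, with light points for CK, dark points for LP and 1 library per point; a point at 0 is a gene listed at 0. PHT1-1 in shoots went from 8.07 to 60.1 TPM and PHT1-4 in roots from 116 to 12.9 TPM.

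The calls in roots and in shoots overlapped in part. Of 21746 birch-like genes measured in both tissues, 2705 were higher in both, against 1765 for independent lists of these sizes, and 1445 were lower in both, against 1146. In opposite directions were 2667, against 2915. Birch-like genes at 1 TPM or more in both LP libraries and under 1 TPM in both CK libraries numbered 1560. Most animal-matched genes found in both LP libraries had that pattern too, and whether these 1560 were birch genes was not tested. Among all genes, 11976 genes shared a direction (8516 for independent lists) and 5453 differed (6849). Of the 11976, 9696 were higher in both tissues. The pattern of at least 1 TPM in both LP and less in both CK libraries also held for 4686 genes without a protein match. It held for 1377 animal-matched genes as well, so the overlap over all genes need not be a birch response. PHT1-4 fell in LP roots (log2 ratio -3.07, -2.47 when scaled) and rose in LP shoots (1.40, 1.28 when scaled); DGD1 likewise fell in roots (-2.77) and rose in shoots (1.49). Across birch-like genes the log2 ratios of roots and shoots had a Pearson correlation of 0.148; genes are not independent replicates.

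Photosynthesis genes stood far higher in shoots than in roots in both media. The birch-like photosynthesis genes summed to 869 TPM in CK roots and 52938 in CK shoots, and to 4159 and 33891 TPM with LP. Over all 70 members the sums were 877 and 55269 TPM, and 4180 and 35066 TPM with LP. Birch-like cell cycle genes summed to 1144 TPM in CK roots and 6230 in CK shoots, and to 674 and 2046 TPM with LP. All 119 members summed to 1570 and 7391 TPM, and to 893 and 2370 TPM with LP. Birch-like phosphate transporters summed to 1078 TPM in roots and 322 in shoots under CK, and to 471 and 574 TPM under LP. The LP order turned when scaled, to 686 in roots and 463 in shoots. Over all 49 members the sums were 1088 and 326 TPM under CK and 662 and 584 TPM under LP, higher in roots in both media. Birch-like lipid remodelling genes were near equal under CK, with 1295 TPM in roots and 1286 in shoots, and stood at 833 and 2062 TPM under LP (1211 and 1665 when scaled). All 43 members summed to 1442 and 1344 TPM under CK and to 871 and 2087 TPM under LP. GDPDL1 and GDPDL3 were large parts of these sums, at 242 and 350 TPM in CK roots and 442 and 341 TPM in LP shoots. Under CK 11343 genes were higher in roots and 23225 in shoots, or 5777 and 14836 among birch-like genes. Under LP the counts were 28886 and 26031, or 6389 and 16879 among birch-like genes, and with median scaling 8889 and 13340, which moved the root share of those calls from 27.5% to 40%.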

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

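The tests of depth in the first and second patterns and of less birch RNA and of tissue make-up in the third were chosen after their result was seen; the other tests and their limits were written down before they were run.

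Animal-matched genes of at least 1 TPM numbered 1670 in LP roots and 1638 in LP shoots, above 148 and 95 in the CK libraries, and 1377 of the 1397 in both LP libraries were under 1 TPM in both CK libraries; by amount, however, animal-matched genes held 0.973% of the TPM in CK roots and 0.915% in LP roots, with medians of 62.6 and 2.91 TPM per gene. Deeper sequencing is argued against in each tissue: of animal-matched genes at 5 TPM or more in the LP library, shortest contigs left out, 79.8% of 480 were listed at 0 in CK shoots and 87.2% of 196 in CK roots, against 8.54% and 19.2% of birch-like genes. A birch response in both tissues is argued against too: the interquartile range of log2 LP root over LP shoot was 0.312 times that of birch-like genes higher in both tissues. The SD of that ratio was 0.405 times theirs (0.72 against 1.79). It measures the same spread in the same genes and so is not separate evidence. The narrow spread is what RNA of another source present in both LP libraries would give. The birch-like genes were not matched to the animal-matched ones on expression. Where such RNA would come from was not tested, and no biological explanation other than a birch response was tested.

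Yeast-matched genes of at least 1 TPM numbered 1323 in LP roots, against 105 in CK roots and 111 in LP shoots. By amount yeast-matched genes held 2.53% of the TPM in LP roots and 0.622% in CK roots. The medians of those of at least 1 TPM were 13.96 and 48.07 TPM per gene. Greater depth of the LP root library is argued against: of 638 yeast-matched genes at 5 TPM or more there, shortest contigs left out, 62.5% were listed at 0 in LP shoots, against 7.43% of birch-like genes. Yeast cells on or in the LP roots, or yeast RNA added later, may account for them, but the test was not decisive: yeast-matched ribosomal protein genes, expected to be abundant in growing yeast, had a median TPM 1.33 times that of the other yeast-matched genes. The design holds 1 LP root library, so growth of yeast without phosphate and a chance growth in this sample cannot be told apart.

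Birch-like phosphate transporters had a median log2 ratio in shoots 1.5 above that in roots, with opposite directions; the difference was not tested, and a root response that differs from that of shoots stays open. Less birch RNA in the LP root library stays open, because scaling moved the root median from -0.98 (interval -1.38 to 0.00) to -0.39 (interval -0.80 to 0.16). Few distinct fragments in the CK root library stay open: the 11 members of at least 1000 bp above 0 in both root libraries had a scaled median of -0.39 (interval -2.36 to 3.34), and 7.30% of 9848 birch-like genes at 5 TPM or more in the other libraries were listed at 0 there, against at most 2.88% for any other library. Exchanged root labels cannot be told apart from correct ones by the 28 phosphate-list genes higher in LP shoots (scaled root median -0.16, interval -1.10 to 0.33). The labels as given go with 4150 birch-like genes that share a direction (2911 for independent lists) and 2667 that do not (2915). Tissues need not respond alike, however. The shared directions may also hold some of the 1560 birch-like genes at 1 TPM or more in both LP libraries and under it in both CK libraries. A different tissue make-up of the libraries also stays open. Birch-like root markers in shoots had a scaled median of 0.0903 with an interval of 0.00 to 0.68 that includes the transporters' 0.41. This list cannot decide the question, because it told roots from shoots weakly. Of its 45 birch-like members 18 were higher in roots and 9 in shoots under CK, and 14 and 19 under LP.

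For photosynthesis genes the medians of birch-like members had opposite signs, and the shoot median minus the root median was -0.87, a difference that was not tested. The GDSL esterase At5g45920 stood at 221 TPM in CK roots and was listed at 0 in LP roots, but went from 1.21 to 65.4 TPM in shoots. Laccase-15 (TT10) stood at 122.8 TPM in CK roots and 24.6 TPM in LP shoots, and the pentatricopeptide protein At2g01390 at 174 and 20.7 TPM, each listed at 0 in the other libraries of that tissue. These 3 are contigs of 203 to 240 bp, and their differences between tissues were not tested.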

How the results depend on the processing

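The settings restricted to birch-like genes, with or without median scaling, and to genes above 0 in every library compared were chosen after the data were seen; the others were fixed before. A pseudocount of 0.1, median scaling over all genes and sums over a shared protein name kept all 10 counts within 1.5 times; leaving out the filter changed nothing, because a log2 ratio of 1 with this pseudocount already needs 1 TPM. A minimum of 5 TPM left 5508 genes with the same and 3249 with opposite directions in the tissues. A log2 threshold of 2 left 8744 lower in LP roots, 8087 lower in LP shoots, and 5716 and 2507 with the same and opposite directions. Birch-like genes alone gave 10098 higher and 8525 lower in LP roots, 8120 and 6484 in LP shoots, 4150 with the same and 2667 with opposite directions, 5777 higher in roots and 14836 in shoots under CK, and 6389 and 16879 under LP. With median scaling these became 11797, 6587, 7510, 6862, 4161, 2543, 6040, 14425, 8889 and 13340. Genes above 0 in every library compared gave, in the same order, 5113, 8542, 6286, 5782, 1963, 1389, 5835, 6225, 9424 and 13107; here fewer genes are counted, and the balance in roots turned to lower. The median log2 ratio of phosphate transporters became -1.52 in roots when summed over a shared protein name. In shoots it became 1.04 at a minimum of 5 TPM. That of phosphatases and nucleases in roots became -0.63 at a minimum of 5 TPM and -0.82 over genes above 0 in both libraries. These values were unscaled, while median scaling placed LP roots 0.63 log2 units below CK roots. The cause of these moves was not tested. The ribosomal list in roots turned from 1.85 to -0.27 when summed over a shared protein name and to -0.75 over birch-like genes. It was -0.16 with their scaling and -1.23 over genes above 0 in both libraries. Of all 714 members 434 were higher and 192 lower, against 95 and 135 of the 297 birch-like ones. The rise over all members therefore lay in members whose best match was not a eudicot. Why the other settings turned it was not tested. Summed over its protein name, histone H3.3 (HHT3) in roots turned to -0.74 and proliferating cell nuclear antigen in shoots to -0.87. Of 54 list medians a minimum of 5 TPM moved 24 and genes above 0 in both libraries moved 20. Of 156 named values, 144 kept their side of the size rule under median scaling. When contigs of a shared protein name were summed, 30 fell short of it and 2 turned. A rise or fall given for 1 contig may therefore not hold for its protein name, and in the Results only PAP3 has its summed value beside it. TMM factors were not run, since the table holds no counts, nor was the stricter threshold on calls by the authors, since no such calls were used here. No library can be left out with 1 per group. Depth limits the low genes: 3 fragments of a 400 bp contig were 0.630 TPM in CK shoots.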

Other observations

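The counts by organism in this part were chosen after the data were seen.

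Single genes of other nutrient and hormone lists passed the size rule. In roots the birch-like nitrogen list had 31 members higher and 29 lower (41 and 19 when scaled), iron 11 and 8 (12 and 6), potassium 13 and 14 (16 and 14), auxin 20 and 44 (29 and 36), and gibberellin and strigolactone 8 and 15 (9 and 13). Over all members nitrogen had 50 higher and 34 lower, iron 15 and 8, and potassium 17 and 14, unscaled. Unscaled, the median of each of these lists was 0.00. Members listed at 0 in both root libraries count as unchanged in these medians. They numbered 32 of 129 birch-like members for nitrogen, 12 of 40 for iron and 20 of 62 for potassium. For auxin they numbered 25 of 131, and for gibberellin and strigolactone 10 of 39. NRT3.1, a partner protein of nitrate transporters, fell in LP roots from 523 to 84.1 TPM and rose in LP shoots from 129 to 380 TPM. In roots ferritin FER2 rose from 82.8 to 480 TPM, the expansin-like EXLB1 from 26.2 to 276 TPM, the auxin response repressor IAA26 from 80.6 to 370 TPM and the trehalose-phosphate synthase TPS9 from 13.8 to 144 TPM. Also in roots, IAA9 fell from 831 to 167 TPM, the potassium channel SKOR, which loads potassium into the xylem, from 112 to 13.9 TPM, and the wall enzyme XTH23 from 333 to 23.0 TPM. TPS7, of the same list as TPS9, fell from 195 to 59.55 TPM (log2 ratio -1.69, -1.08 when scaled). PFP-BETA, a subunit of the pyrophosphate-dependent phosphofructokinase, rose in roots from 57.5 to 212 TPM. Going the other way from the named members of their lists, the iron transporter IRT3 went in roots from 153 to 53.6 TPM (log2 ratio -1.49, -0.88 when scaled), and asparagine synthetase AS1 and the potassium transporter POT12 rose from 48.6 to 118 and from 12.9 to 38 TPM.

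In shoots chalcone synthase (CHS), the entry step of flavonoid synthesis, fell from 383 to 52.7 TPM, while the flavonoid list as a whole had 17 birch-like members higher and 24 lower. The glycerol-3-phosphate transporter At3g47420 rose from 25.2 to 93.3 TPM, sulfate transporter SULTR3;1 from 0.44 to 14.2 TPM and sucrose synthase SUS2 from 41.5 to 119 TPM, whereas the sucrose synthase SS1 fell from 255 to 88.7 TPM. In the list of At3g47420 the ATP-citrate synthase chain ACLA-1 fell from 463 to 161 TPM. Sulfate transporter SULTR3;4 (268 bp) stood at 29.2 TPM in CK and was listed at 0 in LP. The aquaporin PIP1-2 rose from 163 to 430 TPM in shoots. The chloroplast-encoded psbA transcript rose from 16.0 to 108 TPM; poly(A) selection enriches such transcripts poorly.

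The chlorophyll a-b binding protein OsI_012078 stood at 3698 TPM in LP roots, 1612 in LP shoots, 3234 in CK shoots and 187 in CK roots. The sum of the other birch-like photosynthesis genes was 461 TPM in LP roots and 32280 in LP shoots.

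Of the 1397 animal-matched genes in both LP libraries, the best Swiss-Prot match was a cattle protein for 573, a human protein for 344, a fruit fly protein for 146 and a mouse protein for 91. Proteins of the moths Spodoptera frugiperda, Bombyx mori and Manduca sexta gave 23, 21 and 19. Cattle-matched genes had a median log2 LP root over LP shoot of -0.93 and fruit fly-matched genes one of -0.72. The best match names the nearest protein in a database and not the organism itself.

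Genes listed in 1 library alone numbered 2181 in CK roots, 15788 in LP roots, 3777 in CK shoots and 5864 in LP shoots. Their median was 150 fragments in CK roots and 36, 25 and 22 in the others. Birch-like contigs under 300 bp at 50 TPM or more in 1 library and listed at 0 in the other 3 numbered 306 in CK roots, 2 in LP roots, 24 in CK shoots and 3 in LP shoots.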
